A study of Drosophila melanogaster with 4 samples.

How the data were processed

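RNA was sequenced from ovary follicle cells of Drosophila melanogaster in 4 libraries, 2 control and 2 EGFR-activated. Per the labels' protocols, total RNA was isolated with RNAqueous-Micro, enriched by oligo-dT pulldown and made into libraries with ScriptSeq v2. Per the submitters' processing notes, TopHat2 2.0.10, HTSeq 0.6.1 and DESeq2 1.2.10 were used, with the genome build BDGP5. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes may be shared.

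Counts per library were not used in any comparison here; reads of low genes recovered for unassigned libraries are described separately. The authors' deposited table of the comparison gives, for each gene, a mean of normalised counts over all libraries (a signal scaled by size factors, per the file headers), a log2 fold change, its standard error, a Wald score, a p-value and an adjusted p-value. The authors' second deposited table gives log2 fold changes from DESeq2 and Cuffdiff, adjusted p-values, and the penetrance in percent of a phenotype for an RNAi line, per the file headers. Columns that belong to other samples numbered 0. The authors' version of DESeq2, per the submitters' processing notes, shrinks fold changes by default, so folds of low genes may be understated. The Wald score equalled fold change over standard error within rounding.

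The first table has 15687 rows. The 5 rows that name no gene were left out of every test. By mean normalised count, the row for alignments that are not unique made up 41.2% of the total, reads in no gene 4.94% and ambiguous reads 0.896%. Whether the first of these counts a read once or once per alignment was not checked, so it is not a share of reads. Of 15682 genes, 3032 were listed at 0, 12650 had a p-value and 9409 an adjusted p, the lowest of these at a mean of 7.73. Adjusted p-values were used as deposited, at a threshold of 0.05. The median standard error over genes with a mean of at least 50 was 0.28, with 0.20 and 0.42 as the 10th and 90th percentiles.

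The design fixed before the data were examined named edgeR's quasi-likelihood test for counts per library, and the authors' own DESeq2 adjusted p where only their comparison is held. The latter applied. With 2 libraries per group and no values per library in use, no library could be left out and no spread between replicates is printed.

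Gene lists fixed before the data were examined numbered 24, plus ribosomal protein genes by symbol, 25 in all; 16 of 734 entries were not matched, among them an eggshell gene whose symbol stands in the table in the form of a date. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald score of all genes with a p-value, 2-sided, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. This test compares members with the other genes. Of 782 measured list entries, 79 had a p-value but no adjusted p; they enter the tests and medians and count as not past the threshold. A correlation estimated from libraries could not be used, because it needs values per library; a preset of 0.05 was tried instead. Alternatives fixed beforehand were other thresholds and adjustments, centring on the median of all genes (0.07) or of the ribosomal protein genes (0.92), a rank-based list test, a minimum mean of 50, and lists without members of other lists.

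The length correction was chosen after seeing the data. Exonic union lengths came from the BDGP6 annotation by symbol and synonym and were found for 99.2% of 7887 genes with a mean of at least 50. No coordinates were used, because the builds differ. A lowess curve (span 0.3, statsmodels 0.14.6) of fold change on log2 length was subtracted, and p-values were recomputed from the corrected fold change over its standard error. The correction also removes any biology that follows gene length. A further 8 lists, the classes of eggshell genes, the recovered reads and the test on factors of higher penetrance were also chosen after seeing the data.

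Size factors and reads were recovered from the mean normalised counts. A gene with a single read has a mean of 1 over 4 size factors, so the 4 lowest values shared by at least 100 genes each give the 4 size factors. For genes with a mean under 99, whole reads in the 4 libraries that add up to the mean (within 3e-08 below a mean of 10, and 1.5e-08 above) had a single solution in 5339 of 5378 genes. These libraries were not assigned to samples or groups and enter no comparison between groups.

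Genes were named by a rule fixed before the data were examined: Egfr, gro and pnt; the 10 largest changes in each direction among genes past the threshold with a mean of at least 100; up to 4 members per list past the threshold with the smallest adjusted p and a mean of at least 50; factors with a screen phenotype, up to 12; and the 3 largest changes in each direction among the factors. The genes Mkp3, aos, sty, kek1, cas, Fas3, N, Dl, Vml, Yp1, Yp3 and Act57B, and those of the lists added later, were named after their values were seen.

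Steps were tested on simulated data for this comparison. With 9409 genes at their real standard errors, 64% of 100 genes changed by a log2 of 1 and 96% of 100 changed by 2 were called, with 6 unchanged genes called. Reads were recovered exactly in 100% of 4745 simulated genes. With a length trend alone over 7824 genes, the ribosomal protein median went from 0.54 to −0.08 on correction. That trend was the fitted curve itself, so the result checks the steps only. With 12650 genes, a list shifted by 1 unit of the Wald score was called in 100% of 100 draws, and 0.0417% of unshifted lists were called. Scores were drawn independently for each gene, so these shares do not measure the error of the list test on correlated genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.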

Results

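Follicle cells, the somatic epithelium that surrounds the germ line in the Drosophila melanogaster ovary, were profiled by RNA sequencing. The control expressed a membrane-tethered GFP (CD8-GFP) alone. The EGFR-activated cells expressed the same GFP together with lambdatop, an activated form of the epidermal growth factor receptor. There were 2 groups of 2 libraries each, 4 libraries in all. Flies were reared at 18 °C and kept as adults at 29 °C for 7 to 10 days before dissection. The submitters call the replicates biological. Fold changes are EGFR-activated over control on the log2 scale, given with their standard errors, and every fold change, standard error and adjusted p of a single gene is from the authors' deposited table. The mean normalised counts in that table summed to 21565892 over 15682 genes. The size factors behind them, recovered from the lowest values of the table, were 1.46, 1.16, 0.786 and 0.773 for the 4 libraries, which are not tied to groups here.

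The first question was what an activated receptor did to the transcriptome of these cells. Egfr itself, the gene the transgene carries, rose by 1.498 ± 0.35 in the authors' deposited table (adjusted p = 0.000177). All 5 early and 4 late genes examined for the chorion, the outer eggshell, fell. Of 44 junction and polarity genes 21 fell and 1 rose, and of 29 muscle sheath markers 16 fell and 1 rose. On the deposited scale, 25 of 46 cell cycle genes, 52 of 85 ribosomal protein genes and 7 of 12 genes of the Enhancer of split complex rose, with 0 lower in each. After removal of a trend on gene length, 26 of 45, 8 of 80 and 4 of 5 members with a corrected value were higher. Transcripts of gro, which encodes the corepressor Groucho, were at 0.37 ± 0.26 and did not pass the test (adjusted p = 0.272). The ETS factor pnt, a transcriptional effector of the receptor, fell by 1.29 ± 0.26 (adjusted p = 1.19e-05).

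Of 9409 genes with an adjusted p, 1696 were higher and 1644 lower in EGFR-activated cells at an adjusted p under 0.05 in the authors' deposited table. At an unadjusted p under 0.05 there were 4189 genes. The split between higher and lower calls depended on the scaling: 50.8% of calls were higher as deposited, 44.2% after centring on the median of all genes, and 1.79% (96 higher, 5280 lower) after centring on the median of the ribosomal protein genes, which lies at 0.92. Among the 7824 genes with a mean normalised count of at least 50 and a known exonic length, 1668 were higher and 1455 lower, and after removal of a trend on length in these genes 893 were higher and 1317 lower. Centred on the ribosomal protein genes, Egfr was at 0.58 and no longer passed the test. After removal of the length trend Egfr was at 1.91 (adjusted p = 9.48e-07). That value rests on the annotated exonic length of Egfr, 6947 bp, which need not be that of the transgene's transcript. Reads of the transgene and of the native gene were not separated. The ribosomal protein genes are short, with a median exonic length of 903 bp, and their median itself fell on that removal. Centring on them therefore carries part of the length trend.

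Among genes with a mean normalised count of at least 100, the largest fall in the authors' deposited table was that of Hsc70-2, a heat shock cognate gene, at −6.60 ± 0.40 (adjusted p = 8.23e-58). The noncoding genes CR43615 and CR43152 fell (−4.06 ± 0.40 and −3.87 ± 0.44). Fad2, a fatty acid desaturase, and Cyp4g1, a cytochrome P450 of oenocytes that makes cuticular hydrocarbons, fell (−3.32 ± 0.39 and −3.27 ± 0.27). CG7884, PsGEF, CG43333, CG32110 and Tusp completed the 10, at −3.62, −3.31, −3.11, −3.07 and −3.06. The largest rise was that of CG13636, by 3.59 ± 0.50 (adjusted p = 3.92e-11), followed by CG17816 at 3.07 ± 0.23 and CG32447 at 2.998 ± 0.44. Osi6 rose by 2.96 ± 0.37, the small heat shock gene Hsp67Ba by 2.53 ± 0.26, and Pepck, the gluconeogenic phosphoenolpyruvate carboxykinase, by 2.13 ± 0.47. CG32037, nord, Tim9a and clumsy were at 2.81, 2.07, 2.05 and 2.03.

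Eggshell genes were lower in EGFR-activated cells. Of 39 measured yolk, vitelline membrane and chorion genes, 21 fell, 0 rose and 18 did not pass the test in the authors' deposited table; adjusted over the list alone, 21 fell. The median was −1.36 and the list stood apart from the other genes (camera adjusted p = 5.91e-13). CG13114 fell by 2.62 ± 0.19, CG15570 was at −2.72 ± 0.33, CG13084 at −2.21 ± 0.27 and the chorion gene Cp7Fb at −2.28 ± 0.24. All 5 early chorion genes examined and all 4 late chorion genes passed the test, with medians of −2.05 and −2.49. Of 6 vitelline membrane genes, Vml alone passed (−1.36 ± 0.47, adjusted p = 0.0152), and the median was −0.69. None of the 3 yolk protein genes passed; Yp1 was at −0.40 ± 0.46 and Yp3 at −0.82 ± 0.40. Differences between these classes were not tested. In the same libraries muscle sheath and fat body markers had medians of −1.05 and −0.75.

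**Figure D1:**
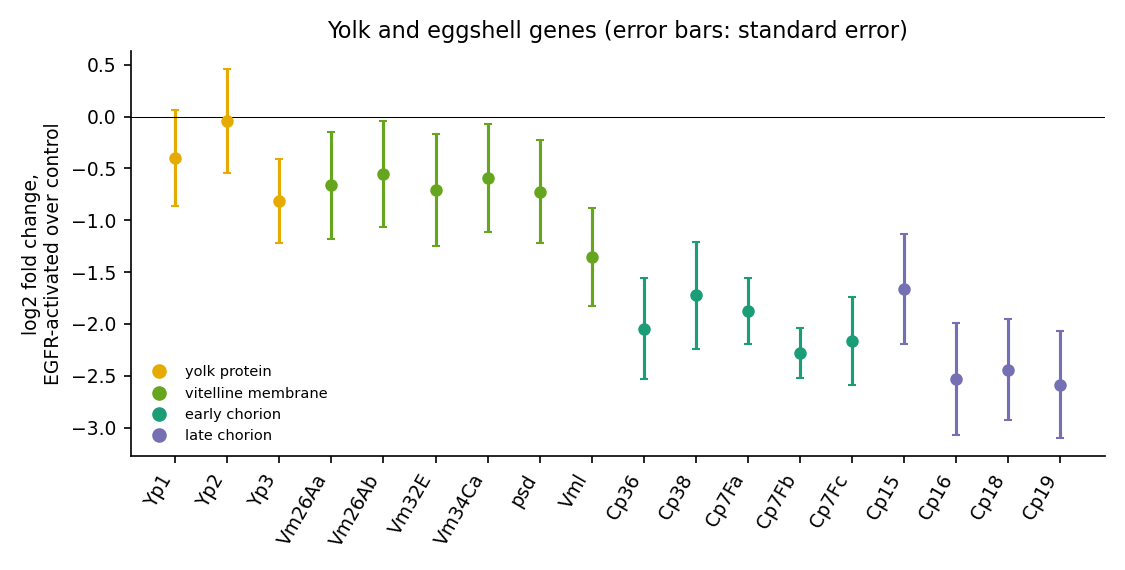
Log2 fold change (EGFR-activated over control) of yolk, vitelline membrane and chorion genes, from the authors' deposited table. Points are genes, bars their standard errors and colours the gene class; the chorion genes lie between −1.66 and −2.59.

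Regulators of main body follicle cell differentiation were also lower. Of 30 measured, 10 fell, 0 rose and 20 did not pass in the authors' deposited table, with 10 lower adjusted over the list alone. The cadherin gene Cad74A fell by 2.40 ± 0.23, the T-box gene H15 was at −1.68 ± 0.29, the zinc finger gene ush at −1.30 ± 0.20 and Sox14 at −1.09 ± 0.22. The median was −0.17 (camera adjusted p = 0.00400). The call ended at a preset correlation of 0.05 (adjusted p = 0.0643), without members of other lists (adjusted p = 0.0829) and after removal of the length trend (adjusted p = 0.525).

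Genes of the early follicle lineage, stalk and polar cells moved both ways. Of 37, 4 rose, 3 fell and 30 did not pass in the authors' deposited table; adjusted over the list alone, 2 rose and 3 fell. The follicle cell fate gene eya was at 0.90 ± 0.25 (adjusted p = 0.00171) and the somatic factor tj at 0.87 ± 0.24 (adjusted p = 0.00216). Both passed the test as deposited and after removal of the length trend (1.05 and 0.98). Both were slightly negative after centring on the ribosomal protein genes. Sox14 fell (−1.09 ± 0.22), and chif was at −0.87 ± 0.25, a call that ended after removal of the length trend (−0.43, adjusted p = 0.200). The list as a whole did not pass (median 0.06, camera adjusted p = 0.851). The polar and stalk lineage gene cas was at 0.40 ± 0.39 and the adhesion gene Fas3 at −0.70 ± 0.33, neither past the test (adjusted p = 0.467 and 0.0788).

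Cell cycle genes were higher in EGFR-activated cells. Of 46 measured, 25 rose, 0 fell and 21 did not pass in the authors' deposited table; adjusted over the list alone, 31 rose and 1 fell. The Drosophila PCNA gene mus209 rose by 1.40 ± 0.19, the licensing inhibitor geminin by 1.21 ± 0.18, the mitotic kinase cdc2 by 1.43 ± 0.24 and the MCM subunit dpa by 1.32 ± 0.23. The median of the list was 0.71 as deposited (camera adjusted p = 7.30e-10) and 0.74 after removal of the length trend (adjusted p = 6.44e-08), and it turned to −0.21 when centred on the ribosomal protein genes, where 1 member (mus209) was higher and 10 were lower past the test.

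Ribosomal protein genes, transcribed in every cell, rose as deposited in 52 of 85 cases, with 0 lower and 33 not past the test; adjusted over the list alone, 67 rose. RpS21 rose by 1.83 ± 0.31 and RpL32 by 1.59 ± 0.31 in the authors' deposited table. RpS23 and RpL11 rose by 1.38 ± 0.29 and 1.35 ± 0.29. The median was 0.92 (camera adjusted p = 7.52e-14), and over the 80 members with a mean of at least 50 it was 0.93 before and 0.34 after removal of the length trend (adjusted p = 0.00125), with 8 members past the test. These genes are short, with a median exonic length of 903 bp.

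The Enhancer of split complex is a cluster of Notch targets whose basic helix-loop-helix products recruit Groucho. Of its 12 genes, a list drawn from the Notch genes after their values were seen and so not tested apart from them, 7 rose, 0 fell and 5 did not pass in EGFR-activated cells (median 1.27, or 0.35 centred on the ribosomal protein genes). In the authors' deposited table HLHmbeta rose by 1.17 ± 0.21, HLHm7 by 1.41 ± 0.33, HLHm3 by 1.37 ± 0.36 and the Bearded family gene m2 by 1.80 ± 0.43. None of these 4 passed after centring on the ribosomal protein genes. After removal of the length trend all 4 passed, at adjusted p of 0.0216, 0.0433, 0.0353 and 0.0213. Genes of the complex are short, with a median exonic length of 978 bp. Over the 5 with a mean of at least 50 the median was 1.41 before that removal and 0.83 after it. The other members were too low to be corrected. In the wider list of Notch pathway genes, 7 of 32 rose, 2 fell and 23 did not pass, the same counts as adjusted over the list alone. The 7 that rose all belong to the complex. The list passed the test (median 0.37, or −0.54 centred on the ribosomal protein genes; camera adjusted p = 0.0345), and the call ended at a preset correlation of 0.05 (adjusted p = 0.194), without members of other lists (adjusted p = 0.400) and at a mean of at least 50 (adjusted p = 0.286, or 0.121 with the length trend removed from those genes). Notch itself (N) was at 0.00 ± 0.31 and its ligand Dl at 0.39 ± 0.20, neither past the test.

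In the list of Groucho and DNA-binding repressors that partner with it, 8 of 41 rose, 5 fell and 28 did not pass, also adjusted over the list alone. Six4, a homeobox gene of muscle and gonad development, rose by 1.70 ± 0.21 and the repressor hkb by 1.201 ± 0.29 in the authors' deposited table; hkb no longer passed when centred on the ribosomal protein genes. The list as a whole did not pass (median 0.11, camera adjusted p = 0.231).

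Of 37 components and feedback targets of the receptor's own pathway, 1 rose (Egfr), 6 fell and 30 did not pass in the authors' deposited table; adjusted over the list alone, 1 rose and 7 fell. The phosphatase gene csw fell by 1.35 ± 0.21 and the scaffold gene ksr was at −1.19 ± 0.22. Of feedback targets, the phosphatase gene Mkp3 fell (−0.90 ± 0.26, adjusted p = 0.00263), a call that ended after removal of the length trend (adjusted p = 0.0517). The antagonist aos was at −0.36 ± 0.30, sty, which encodes Sprouty, at 0.44 ± 0.35, and kek1 at −0.58 ± 0.29, none of these past the test. The list did not pass as a whole (median −0.15, camera adjusted p = 0.0973; 2 higher, 5 lower and adjusted p = 0.994 after removal of the length trend).

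BMP pathway genes were lower. Of 23, 2 rose, 6 fell and 15 did not pass in the authors' deposited table, with 1 higher and 6 lower adjusted over the list alone. The protease gene tok fell by 2.08 ± 0.23, the secreted antagonist sog was at −2.07 ± 0.35, magu at −1.45 ± 0.18 and cv-2 at −1.08 ± 0.25. The list passed (median −0.34, camera adjusted p = 0.0145), and the call ended at a preset correlation of 0.05 (adjusted p = 0.0966) and after removal of the length trend (adjusted p = 0.349).

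Among Hippo pathway genes, 2 of 18 rose, 8 fell and 8 did not pass; adjusted over the list alone, 3 rose and 8 fell. The core component sav fell by 1.38 ± 0.20, the apical determinant crb was at −1.27 ± 0.16, Mer at −1.16 ± 0.19 and th, which encodes the caspase inhibitor Diap1, at −1.08 ± 0.22 in the authors' deposited table. The list passed (median −0.27, camera adjusted p = 0.0243). Its call ended in the rank-based test (adjusted p = 0.0786), at a preset correlation of 0.05 (adjusted p = 0.103), without members of other lists (adjusted p = 0.212) and after removal of the length trend (adjusted p = 0.205).

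The Hedgehog, Wnt and JAK-STAT lists did not pass as wholes (camera adjusted p = 0.940, 0.975 and 0.975). Of 19 Hedgehog pathway genes 2 rose and 3 fell (1 and 3 adjusted over the list alone); the kinase gene fu was at −0.87 ± 0.20, botv at −0.93 ± 0.28, rdx at −0.87 ± 0.34 and the glypican gene dlp at 1.09 ± 0.37 in the authors' deposited table. Of 28 Wnt pathway genes 1 rose and 1 fell, also adjusted over the list alone; Wnt5 was at 0.91 ± 0.29, or −0.01 centred on the ribosomal protein genes, and Apc at −0.68 ± 0.20. Of 17 JAK-STAT genes 1 rose and 2 fell, also adjusted over the list alone; the transcription factor Stat92E rose by 1.03 ± 0.25, while the Janus kinase gene hop fell by 0.99 ± 0.24 and the receptor gene et was at −0.89 ± 0.29. The calls of dlp and Stat92E ended when centred on the ribosomal protein genes (0.17 and 0.11), and those of rdx and Apc after removal of the length trend (−0.47 and −0.22). After that removal Wnt5, dlp and Stat92E passed, at 1.10, 1.25 and 1.34.

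Junction and polarity genes were lower in EGFR-activated cells. Of 44, 1 rose, 21 fell and 22 did not pass in the authors' deposited table, the same counts higher and lower as adjusted over the list alone. Gli, which encodes gliotactin of tricellular junctions, fell by 1.69 ± 0.22, Mcr was at −1.51 ± 0.18, cold at −1.31 ± 0.18 and crb at −1.27 ± 0.16. The median was −0.61 (camera adjusted p = 1.51e-08), and over the 41 members with a mean of at least 50 it was −0.67 before and −0.23 after removal of the length trend (adjusted p = 0.00218). After it 17 of the 41 were lower and 3 higher past the test. Members of this list are long, with a median exonic length of 5999 bp, and muscle sheath markers had a median of −1.05 in the same libraries.

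Extracellular matrix genes included the type IV collagen genes vkg and Cg25C, which rose by 1.12 ± 0.16 and 1.07 ± 0.16 in the authors' deposited table. These calls ended when centred on the ribosomal protein genes (0.20 and 0.15), while both passed after removal of the length trend (1.52 and 1.45). Plod, a collagen lysyl hydroxylase gene, rose by 1.52 ± 0.25, and the matrix metalloproteinase gene Mmp2 fell by 1.38 ± 0.26. Of 21 members 7 rose, 3 fell and 11 did not pass; adjusted over the list alone, 7 rose and 4 fell. The list did not pass as deposited (median 0.23, or −0.69 centred on the ribosomal protein genes; camera adjusted p = 0.0917) and passed after removal of the length trend (adjusted p = 0.000142), with a median of 0.55 over the 18 members with a mean of at least 50, against 0.46 before the removal.

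Ecdysone genes moved both ways. Of 29, 9 rose, 7 fell and 13 did not pass in the authors' deposited table; adjusted over the list alone, 9 rose and 8 fell. Cyp18a1, which inactivates ecdysone, rose by 1.70 ± 0.23 and nvd, an enzyme of its synthesis, by 1.47 ± 0.30; nvd no longer passed when centred on the ribosomal protein genes (0.55). The response factor Eip74EF fell by 1.09 ± 0.24 and the secreted insulin antagonist ImpL2 was at −1.58 ± 0.29. The list did not pass (camera adjusted p = 0.975), with a median of −0.12 and a test direction of higher.

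Of 24 genes of JNK signalling and apoptosis 3 rose and 10 fell, also adjusted over the list alone. The relaxin-like gene Ilp8 fell by 2.14 ± 0.23, CG10176 was at −1.74 ± 0.27 and the filamin gene cher at −1.26 ± 0.22, and scaf rose by 1.98 ± 0.32 in the authors' deposited table. The list did not pass (median −0.14, camera adjusted p = 0.0917). Heat shock genes split, with 5 of 23 higher and 3 lower, also adjusted over the list alone (median 0.16, camera adjusted p = 0.272). Hsp67Bc and Hsp60 rose by 1.80 ± 0.27 and 1.10 ± 0.26, the latter not past the test when centred on the ribosomal protein genes (0.18); Hsp70Bc was at −2.23 ± 0.25, an uncertain value because near-identical copies share its reads. Of 36 immune effector genes 8 fell and 0 rose, also adjusted over the list alone; the NF-kappaB gene Rel fell by 1.32 ± 0.18, PGRP-LB was at −1.59 ± 0.28, TepII at −1.15 ± 0.30 and TepIV at −0.97 ± 0.23. That list passed narrowly (median −0.42, camera adjusted p = 0.0480). The call ended at a preset correlation of 0.05 (adjusted p = 0.223), at a mean of at least 50 (adjusted p = 0.0628), without members of other lists (adjusted p = 0.0594) and with centring on the median of all genes (adjusted p = 0.0623). Fat body and oenocyte markers had a median of −0.75 in the same libraries.

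Markers of other cell types moved with the groups. Of 29 muscle sheath markers 1 rose, 16 fell and 12 did not pass in the authors' deposited table (2 and 18 adjusted over the list alone), with a median of −1.05 (camera adjusted p = 2.48e-05). The paramyosin gene Prm fell by 2.22 ± 0.29, the myosin heavy chain gene Mhc was at −1.91 ± 0.39, Tm2 at −1.68 ± 0.28 and Msp-300, a gene of long transcripts, at −1.49 ± 0.31, which was −0.57 and not past the test after removal of the length trend (adjusted p = 0.160). Of 18 fat body and oenocyte markers 1 rose and 7 fell, also adjusted over the list alone (median −0.75, camera adjusted p = 2.48e-05). Besides Cyp4g1, v(2)k05816, a fatty acid synthase gene, fell by 2.66 ± 0.35, the lipophorin gene Rfabg was at −2.002 ± 0.22 and the lipase gene bmm at −1.62 ± 0.19. These falls stood beside those of the eggshell and junction genes.

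Germ cell, hemocyte, neuron and escort cell lists did not pass (camera adjusted p = 0.272, 0.802, 0.0718 and 0.407); the neuron list passed in the rank-based test (adjusted p = 0.0227). Of 40 germ cell markers 4 rose and 2 fell (3 and 0 adjusted over the list alone, median 0.27); the piRNA pathway genes mael and spn-E rose by 1.06 ± 0.20 and 0.98 ± 0.22, nclb rose by 1.15 ± 0.29 and stau was at −0.53 ± 0.21 in the authors' deposited table. The calls of mael, spn-E and nclb ended when centred on the ribosomal protein genes, and that of stau after removal of the length trend. Of 21 hemocyte markers 3 rose and 3 fell, also adjusted over the list alone; the GATA factor srp fell by 1.53 ± 0.25 and ush fell, while vkg and Cg25C rose. Of 23 neuron markers 0 rose and 4 fell, also adjusted over the list alone; cpx fell by 1.83 ± 0.39, futsch was at −1.32 ± 0.29, Syx1A at −1.10 ± 0.28 and unc-13 at −0.84 ± 0.21, and the calls of futsch and unc-13 ended after removal of the length trend (−0.64 and −0.16). Of 22 escort cell and terminal filament markers 5 rose and 2 fell (4 and 2 adjusted over the list alone); hkb and tj were among the former, Act5C fell (−0.55 ± 0.17) and Pdk1 was at −0.90 ± 0.23, a call that ended after removal of the length trend (−0.50).

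**Figure D2:**
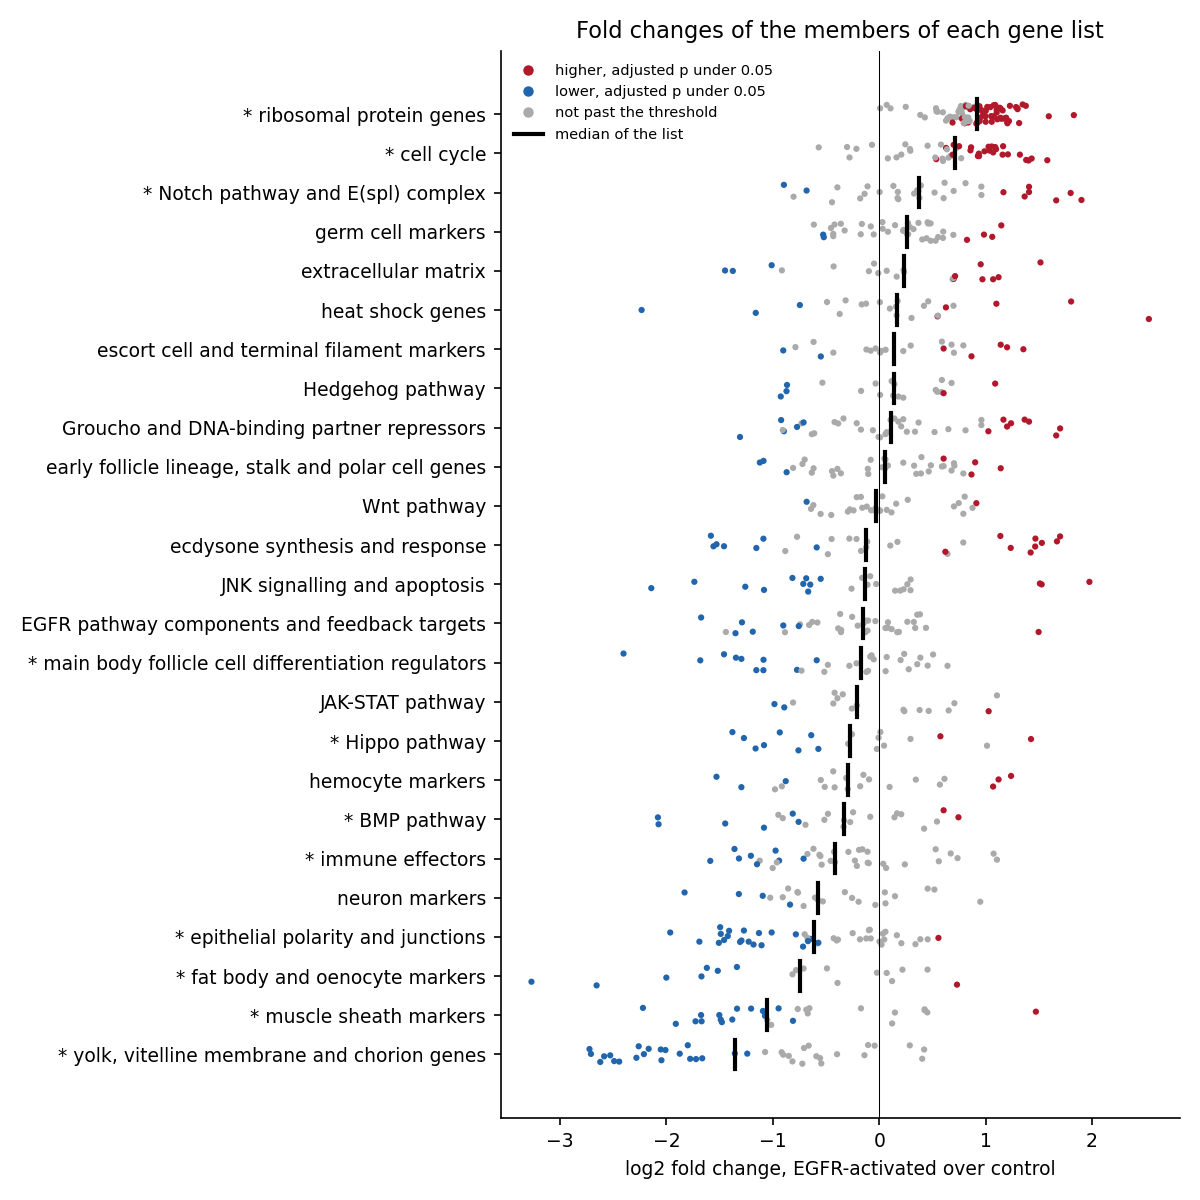
Log2 fold change (EGFR-activated over control) of each measured member of the 25 gene lists, from the authors' deposited table. Points are genes, black bars list medians, red and blue mark members past an adjusted p of 0.05, and an asterisk marks the 11 lists past the camera threshold; medians run from −1.36 for eggshell genes to 0.92 for ribosomal protein genes, and on a scale centred on the ribosomal protein genes the cell cycle median turns to −0.21.

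Fold changes followed gene length. Over 7824 genes with a mean normalised count of at least 50, Spearman's rho of exonic length and fold change was −0.45, a value across genes, which are not independent replicates. Within 3 equal bins of mean count it was −0.39, −0.39 and −0.43. In the shortest 10% of genes the median fold change was 0.76 and 45.4% were called higher, against −0.48 and 3.32% in the longest 10%. Of 3123 calls among these genes, 1796 (57.5%) kept their direction and passed after the length trend was removed, and 0 passed in the opposite direction. The count of alignments that are not unique, which stands outside the gene rows, was lower by 1.96 ± 0.36 in EGFR-activated libraries. Reads in no gene were at −1.31 ± 0.22, per the authors' deposited table.

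**Figure D3:**
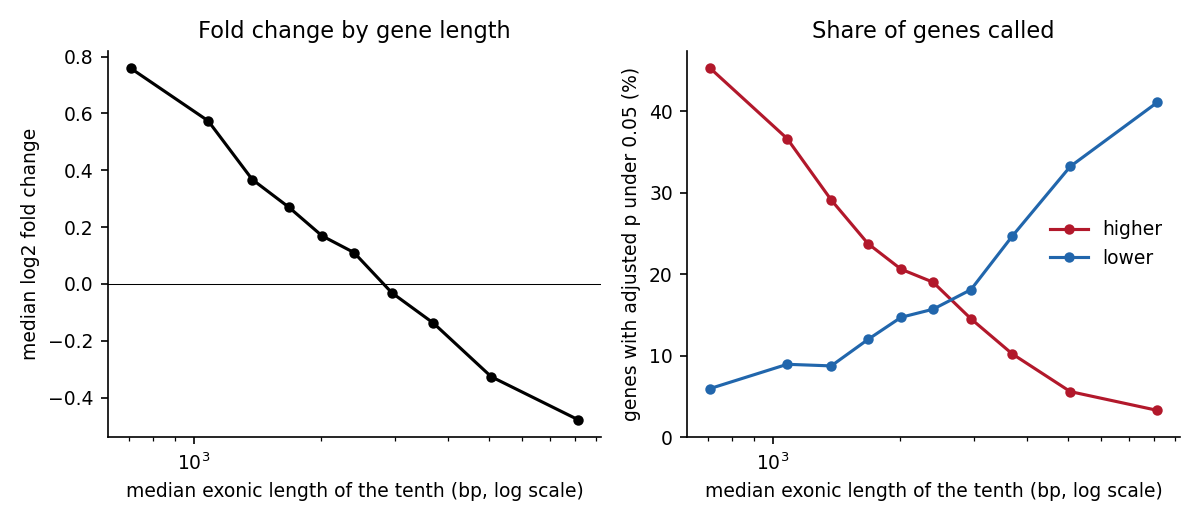
Median log2 fold change (left) and percent of genes called higher or lower at an adjusted p under 0.05 (right) in 10 equal bins of genes by exonic length (bp, log scale). Medians run from 0.76 in the bin of shortest genes to −0.48 in that of the longest.

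The second question was which transcription factors changed and whether their knockdown by RNA interference gave a phenotype in early follicle cells. The authors' second deposited table lists 40 factors, 14 higher and 26 lower in EGFR-activated cells. The largest rises were those of Six4 (1.70 ± 0.21), HLHmgamma (1.66 ± 0.46) and Ssb-c31a (1.63 ± 0.24); HLHmgamma no longer passed when centred on the ribosomal protein genes (0.75). The largest falls were those of Mrtf, a cofactor of serum response factor, at −2.14 ± 0.33, the bHLH-PAS factor sim at −1.95 ± 0.22 and the POU factor vvl at −1.64 ± 0.50. The factors were chosen on these libraries, so their count is not independent evidence of change. The share higher, 35.0%, did not differ past the threshold from 51.0% among the other called genes (2-sided Fisher's exact p = 0.0554); against 53.2% among all genes with an adjusted p it did (p = 0.0255), and against 48.5% among genes past an adjusted p of 0.01, which all 40 factors passed, it did not (p = 0.110). All 40 had the same direction in DESeq2 and Cuffdiff, and 16 were past an adjusted p of 0.01 in both, per the authors' deposited table. After removal of the length trend, 29 of the 40 passed at 0.05 in the same direction. On that scale 40.4% of the calls among 7824 genes with a mean of at least 50 and a length were higher. The direction of the factors was not tested there, so a part of gene length in the comparisons above is not excluded.

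Screen results were recorded for 26 factors, of which 10 had a phenotype and 16 had none. Six4 had the highest penetrance, above 90%, followed by Mrtf at about 50% and the gene for heterochromatin protein HP1a at about 25%. The other 7, pnt, srp, HLHm3, HLHm7, Hr46, Mef2 and su(Hw), were below 15%. Of the latter, su(Hw) was at 0.80 ± 0.19, Hr46 at −1.46 ± 0.36 and Mef2 at −1.07 ± 0.27 in the authors' deposited table, and the HP1a gene was at 0.91 ± 0.29; su(Hw) and the HP1a gene were negative after centring on the ribosomal protein genes. The calls of the HP1a gene and Mef2 ended after removal of the length trend (0.40 and −0.59, adjusted p = 0.331 and 0.0800). Factors with a phenotype were split 5 higher and 5 lower, and those without 3 higher and 13 lower (2-sided Fisher's exact p = 0.189). The median absolute log2 fold change was 1.39 with a phenotype and 1.06 without, a difference that did not pass a 2-sided permutation test (p = 0.179, 100000 resamples). Factors are not replicates of each other. The sources used here do not give the definition of a phenotype, the number scored or the strength of a knockdown. A record of no phenotype therefore does not show that a factor is not needed.

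**Figure D4:**
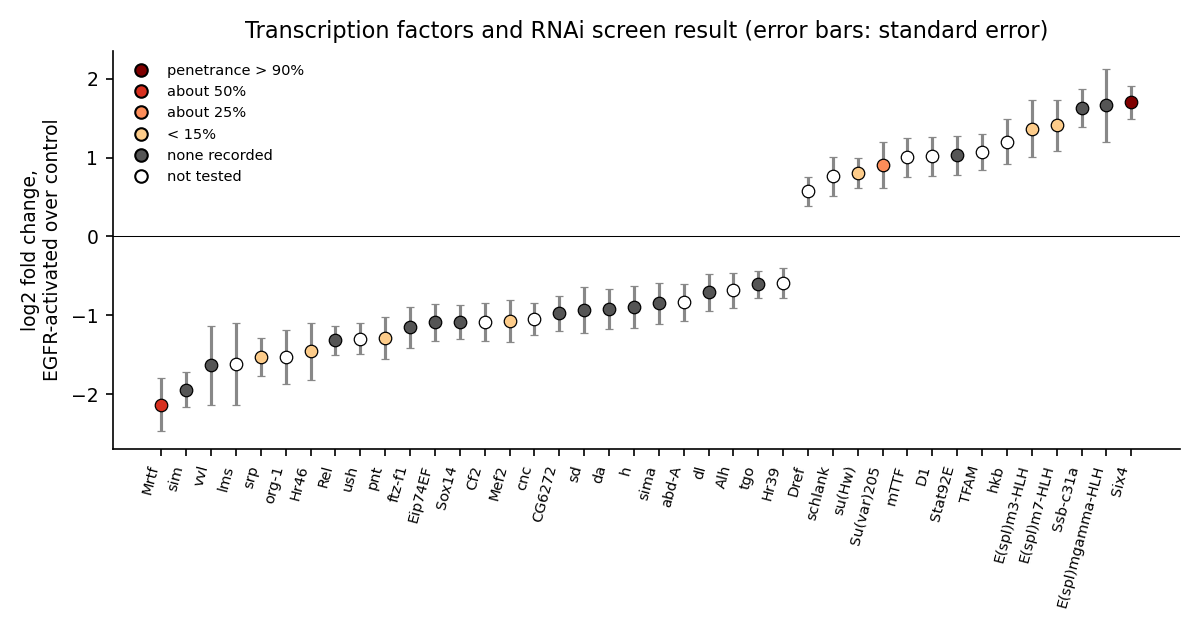
Log2 fold change (EGFR-activated over control) of the 40 transcription factors of the authors' second deposited table, in order of fold change. Points are factors with standard errors, colours give the recorded penetrance in the RNAi screen, dark grey no phenotype and white not tested; Six4 and Mrtf stand at the ends, at 1.70 and −2.14.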

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

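The length correction with its gene filter, the background of genes past an adjusted p of 0.01 and the comparison of factors with a penetrance of about 25% or more were chosen after seeing the data; the other alternatives were fixed before the data were examined. No paired analysis was possible because the columns used here are pooled over libraries or belong to a comparison, with none per library. The fits with edgeR and DESeq2 on counts, the filter on low counts and the omission of each replicate were not run, because they need counts per library, which are not used here. Genes higher and lower numbered 1696 and 1644. They became 927 and 1031 with the Benjamini-Yekutieli adjustment, 777 and 982 with an absolute log2 fold change of at least 1, and 96 and 5280 when centred on the ribosomal protein genes. Those higher became 1102 at a threshold of 0.01. Among 7824 genes with a mean of at least 50 and a length, those higher and lower were 1668 and 1455, and 893 and 1317 after length correction. Stricter thresholds lower counts by construction, and the cause was not tested for the others. Of 25 lists, 11 passed as deposited, 6 at a preset correlation of 0.05, 11 in the rank-based test, 9 at a mean of at least 50, 10 centred on all genes, 7 without shared members and 8 after length correction. At the preset of 0.05, which assumes more correlation by construction, adjusted p became 0.0643 for main body regulators, 0.194 for Notch, 0.0966 for BMP, 0.103 for Hippo and 0.223 for immune effectors. Without shared members, which leaves fewer genes, it became 0.0829 for main body regulators, 0.400 for Notch, 0.212 for Hippo and 0.0594 for immune effectors. After length correction, which takes genes with a mean of at least 50, it became 0.525 for main body regulators, 0.349 for BMP and 0.205 for Hippo. At that mean without the correction it became 0.286 for Notch (0.121 with it) and 0.0628 for immune effectors; Hippo was at 0.0786 and neuron markers, not past the test as deposited, at 0.0227 in the rank-based test, and immune effectors at 0.0623 centred on all genes. The cause was not tested. The eggshell, cell cycle, ribosomal, junction, muscle and fat body lists passed in every list setting run. Centred on the ribosomal protein genes, Egfr was at 0.58 (adjusted p = 0.148), and gro turned to −0.55, eya to −0.017, tj to −0.051, Wnt5 to −0.0053, su(Hw) to −0.117 and the gene for heterochromatin protein HP1a to −0.011, by the construction of that scale. Of the other named genes, 88 stayed on their side of the threshold there and 21 no longer passed. After length correction, with the length of the annotated gene, Egfr was at 1.91 (adjusted p = 9.48e-07). Of all other named genes with a corrected value, those that turned above included, 102 stayed on their side and 10 no longer passed. The direction of the factors passed against all genes with an adjusted p (2-sided Fisher's exact p = 0.0255) but not against genes past an adjusted p of 0.01 (p = 0.110). It was not tested after length correction. For the screen, mean normalised count, a different quantity from fold change, was lower in factors with a phenotype, not past the test (permutation p = 0.582). In absolute fold change, factors of about 25% penetrance or more against the rest gave an exact permutation p of 0.0538. Under a mean of 7.73 no gene had an adjusted p in the authors' deposited table.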

Other observations

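The gene lists here and the tests on muscle and late-stage genes were chosen after the data were seen; the tests on length were fixed before their corrected values were seen, but after the length trend and the uncorrected medians had been. The errors of the corrected medians were added after those values were seen. Mitochondrial ribosomal protein genes rose in 61 of 71 cases with 0 lower in the authors' deposited table (median 1.16, or 0.24 with 10 higher when centred on the ribosomal protein genes; camera adjusted p over 8 added lists = 1.67e-25; 0.49 and 3.85e-07 after length correction). Proteasome subunit genes rose in 18 of 24 cases (median 0.84, or −0.08 centred on the ribosomal protein genes), mitochondrial import genes in 7 of 12 (median 0.94, or 0.02) and aminoacyl tRNA synthetase genes in 9 of 21 (median 0.47, or −0.45), with 0 lower in each. All 6 ecdysone synthesis enzymes examined rose, with a median of 1.44, or 0.53 centred on the ribosomal protein genes, where 0 of the 6 passed: besides nvd, phm rose by 1.14 ± 0.26, dib by 1.67 ± 0.56, sad by 1.47 ± 0.50, spo by 1.42 ± 0.50 and shd by 1.24 ± 0.51.

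Septate junction genes, which seal the epithelium, fell in 14 of 17 cases with 0 higher (median −1.31, or −1.12 after length correction). The ecdysone enzymes and septate junction genes were drawn largely from lists reported above after their values were seen, so no test is given for them. Of 83 cytochrome P450 genes with Cyp symbols, which leave out the P450 enzymes of ecdysone synthesis above, 27 fell and 2 rose (median −0.46, camera adjusted p = 4.13e-06). Fat body and oenocyte markers, among them the P450 gene Cyp4g1 (−3.27 ± 0.27), were lower in the same libraries (7 of 18, median −0.75), and library Q of the recovered reads, tied to no group, was highest for 12 of 20 midgut genes.

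Short genes were higher and long genes lower in EGFR-activated libraries, as a length bias of libraries could give. After the length trend was removed the cell cycle median was 0.7356 (adjusted p = 6.44e-08) and the eggshell median −1.911 (adjusted p = 7.12e-15). The median lengths of these lists, 2747 and 1431 bp, lie in bins of genes with median fold changes of −0.03 and 0.37. There the trend is near 0 or of the opposite sign, so its removal could hardly have ended either difference. These lengths argue against the trend as the whole of either. The ribosomal protein median went from 0.93 to 0.3367 (standard error 0.0404, adjusted p = 0.00125), so most of that rise may follow length. The tables argue against the fitted trend as the whole of it, though 8 of 80 members passed as higher, against 893 of 7824 genes. Length here is an exonic union, and whether a closer measure of length would remove the rest was not tested. The junction median went from −0.67 to −0.2307 (standard error 0.153, adjusted p = 0.00218), between the bounds set beforehand. By the median, a length effect therefore cannot be told apart from a change in those genes. The list still passed, with 17 of 41 members lower and 3 higher, against 1317 lower and 893 higher of 7824 genes. Whether the trend arose in the cells or in library preparation stays open, since it goes with the groups.

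Muscle sheath markers were lower in EGFR-activated libraries, and carried-over muscle in the control libraries is a candidate source. Of 23 structural genes, 4 had a mean normalised count above that of Mef2 (1531), fewer than carried-over muscle was taken to bring. Mhc was at 283 and Act57B at 133, while Prm was at 1653 and Msp-300 at 18515. These counts are pooled over all libraries and not scaled by length, and no profile of muscle was measured. They therefore cannot decide the source of the fall of Mef2. That fall did not pass after removal of the length trend (−0.59, adjusted p = 0.0800). For the structural genes themselves, 11 of 23 fell and 1 rose, which lies between the bounds, so carried-over muscle cannot be told apart from a change in follicle cells. The fat body and oenocyte markers, which were lower as a list, were not tested for carry-over.

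The chorion genes examined fell and 25 of 46 cell cycle genes rose, which a smaller share of late-stage follicle cells in the EGFR-activated libraries could give. Such a share predicts equal falls of genes of the same stage. The 4 late chorion genes spanned 0.9222 on the log2 scale against a standard error of a difference of 0.736. That error takes the genes as independent, though they share the same libraries, and a range over 4 genes is not a single difference. The span therefore neither excludes nor requires such a share. A smaller share of late cells and slower maturation of every cell cannot be told apart, because these are bulk libraries without values per cell. A biological effect of the receptor on differentiation stays among the open explanations, as untested.

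In the recovered reads of genes with a mean from 12 to 99, the 4 libraries, named P to S by size factor, fell into pairs. Pearson's r of log2 normalised reads plus 1 across 1758 genes, which are not independent replicates, was 0.572 for P and Q and 0.727 for R and S, against 0.344, 0.373, 0.325 and 0.323 for P and R, P and S, Q and R, and Q and S. Of 20 midgut genes with at least 20 reads, 12 were highest in library Q, 1 in P, 3 in R and 4 in S, and their median normalised reads were 54.4, 14.4, 31.2 and 22.6; over all 2500 such genes 26.4% were highest in Q. Normalised reads of 178 small nucleolar RNA genes summed to 965, 1062, 1774 and 792 in P, Q, R and S.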
